A study of Mus musculus with 2 samples.

How the data were processed

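The series compares monoclonal immortalized mouse mesenchymal stromal cells (MSCs, called fibroblasts in the sample titles) that lack Dicer, the ribonuclease that cuts microRNA precursors, with cells of the same kind that carry it. The labels describe 2 samples, 1 per genotype, of chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against acetylated lysine 27 of histone H3 (H3K27ac). The design text speaks of 2 replicates per genotype, and the headings of the H3K27ac lists say that replicates were pooled. The lists for H3K4me3 and H3K36me3 carry the same genotype names but no sample of their own in the labels used here, and whether their replicates were pooled is not stated in them.

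Alignment was to mouse build mm9, and TopHat 1.4 is named, per the submitters' processing notes, without its role. The 6 deposited lists, 1 per mark and direction, hold predicted binding events from GPS (both H3K27ac lists and the H3K36me3 list of the knockout) or GEM (both H3K4me3 lists and the H3K36me3 list of the wild type), per the file headers and names. GPS and GEM place point events in ChIP-seq data and share reads between neighbouring events; their versions are not given in the sources used here. In each list 1 genotype was the immunoprecipitate and the other the control. Names of the H3K27ac and H3K4me3 lists also mention a DNase data set of wild-type fibroblasts, whose role is not stated. Those of the H3K4me3 and H3K36me3 lists hold the words noControl and defaultDist, and those of the H3K27ac lists the word Newdist. These words are not explained, so settings may differ between marks.

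Each deposited event has an estimated count, the reads that the authors' software assigned to the event in the higher genotype, which need not be whole. It also has a scaled signal for the other genotype, per the file headers in the control column. The deposited fold is the ratio of these values, with a place-holder where the control was 0. A further deposited column of expected signal holds 1 value per chromosome for H3K27ac and H3K4me3 and a local value for H3K36me3. It is called background reads here, although the sources used here do not define it. The deposited −log10 q and p values are limited at 999, and every list starts at a −log10 q of 2, the authors' threshold. These q values were used only to describe, rank and filter events within a list.

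From the lists, the factor by which the other genotype had been scaled was recovered as the step between 0.3 and 3 (tried every 0.0005) that made most control values whole multiples, within 0.06 of the file's units, among events whose own count was whole. In the lists of the knockout the wild type had been multiplied by 0.85 for H3K27ac, 2.15 for H3K4me3 and 0.575 for H3K36me3. In the lists of the wild type the knockout had been multiplied by 1.09, 0.461 and 1.70. At these factors 54.3% to 96.3% of the values were whole, the lowest for the wild-type H3K4me3 list. The ratio reported for an event is its estimated count over the other genotype's scaled reads. Its 95% interval is the exact conditional binomial (Clopper-Pearson) interval of the 2 unscaled read numbers, rounded to whole reads. Shares have exact Clopper-Pearson intervals. Intervals cover counting error only, with reads or events taken as independent, and they leave out replicate and clone error. Reads without molecular identifiers are not independent molecules, so the ratio intervals can be too narrow even for counting error. Where the other genotype had 0 reads, the ratio is given at a floor of 3 reads, which takes the higher genotype's reads as exact. The lower limit of the interval, given beside it, is smaller and is the bound to use.

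Events of different marks counted as neighbours within 1 kb. Expected numbers came from 10000 random placements of each chromosome's events between that chromosome's first and last event. Such placement takes no account of where marked chromatin lies, so shuffles of direction within chromosomes, which keep the positions, were also drawn 1000 times. Events of 1 list within 5 kb were merged into regions, and events of all lists within 10 kb into shared regions. As a second scale for H3K27ac and H3K4me3, chosen after seeing the data, each genotype's unscaled reads were divided by its own background reads on the same chromosome. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. On 6 simulated lists, the step search recovered the simulated factors with an error of 0. Those factors lay on the searched steps, all counts of the higher genotype were whole, and most control values were whole multiples. The wild-type H3K4me3 list, with 20.6% whole counts and 54.3% whole values at its factor, was harder than this setting. The simulation therefore does not check its factor. Among 8314 H3K27ac events, 200 of 200 planted neighbours were found, and 24 unrelated neighbours stood against a median of 17 by random placement. The planted neighbours were put within 1 kb, so finding them checks the code only. The share intervals covered the true value in 380 of 400 draws and the ratio intervals in 386 of 400. These draws were independent whole counts, for ratios at 1 factor. They do not check events with estimated counts that are not whole or with few reads in the lower genotype.

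No test across samples was made, because the lists give 1 value per genotype and mark: no difference below has a replicate check, and none is called changed on the strength of these lists. Total reads per library are not part of the lists, so the depth per sample is unknown. The events named were chosen before the data were examined: per list the 10 with the largest −log10 q, the 5 with the largest ratio among those with at least 50 reads, and the 5 longest regions. Shared regions and regions with opposite directions were picked after their values were seen. The gene table used here is for build GRCm38 and the lists are in mm9, so regions are named by position as the lists give it, and no coordinates were converted. The planned gene lists, the location of events relative to genes, and the check of the Dicer gene itself were therefore not analysed here. Alternatives planned before the data were examined were a stricter q, a 2-fold minimum, a minimum of 50 reads, merging, leaving out the sex chromosomes, other neighbour distances and 1 added read.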

Results

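Histone marks were compared between Dicer knockout (KO) and wild-type (WT) mesenchymal stromal cells of the mouse, grown as monoclonal immortalized lines. H3K27ac is found at active enhancers and promoters, H3K4me3 at promoters, and H3K36me3 along transcribed gene bodies. For each mark, 1 list held the events with more reads in KO and 1 the events with more reads in WT, each with the reads of both genotypes. Together the 6 lists held 21418 events. The labels give 1 sample per genotype, for H3K27ac, and the lists give 1 value per genotype for every mark, with any replicates pooled or not separated, so no replicate error can be given. Total reads per library are unknown, and the reads behind each event set the precision: the median event had 373 reads in KO and 304 in WT for H3K27ac, 231 and 558 for H3K4me3, and 40 and 73 for H3K36me3, in the genotype where it was higher. Positions are in mm9.

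The first comparison asked where H3K27ac differed between cells with and without Dicer. More events were higher in KO than in WT: 8323 against 1765, a KO share of 82.5% (95% interval 81.7 to 83.2). The event with the largest −log10 q in KO lay at 92098909 on chromosome 15, where 3362 reads in KO stood against 684 scaled reads in WT, a ratio of 4.91 (4.55 to 5.32). Beside it, 92106978 to 92132318 on chromosome 15 was the longest region higher in KO, with 16 events over 25341 bp and a ratio of 3.15 (3.05 to 3.25). Other leading KO events were at 30606533 on chromosome 6 (ratio 5.95, 5.31 to 6.69), 13820401 on chromosome 17 (5.59, 4.96 to 6.33) and 9552456 on chromosome 1 (14.6, 11.6 to 18.7). The largest KO ratios were 32.4 (18.8 to 61.8) at 8120700 on chromosome 17 and 22.6 (16.7 to 32.3) at 49164356 on chromosome 6. The next, 20.9 (11.1 to 44.5), was on an unplaced contig. Long KO regions were also seen at 120984106 to 121005173 on chromosome 11 (ratio 4.72, 4.43 to 5.04) and at 41221537 to 41240900 on chromosome 12 (3.75, 3.53 to 3.99).

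In WT, 4 of the 10 leading H3K27ac events lay within 24166214 to 24177414 on chromosome 2, and the one with the largest −log10 q had 1023 reads in WT against 61.5 scaled reads in KO, a ratio of 16.6 (12.8 to 22.3). The events at 45261569 on chromosome 11 (ratio 17.2, 12.9 to 23.0) and 96981877 on chromosome 8 (19.3, 14.0 to 28.1) were of similar size. The largest WT ratio was 34.6 (21.2 to 59.2), at 43597965 on chromosome 18, followed by 32.5 (19.4 to 60.5) at 89841769 on chromosome 8. The longest WT region ran from 25220294 to 25239395 on chromosome 16, with a ratio of 3.84 (3.53 to 4.18). A shorter one, 57996383 to 58010685 on chromosome 9, held 6 events and had a ratio of 16.4 (14.0 to 19.3). The median event differed 2.87-fold in the KO list (quartiles 2.36 and 3.66) and 3.86-fold in the WT list (2.83 and 5.98). Merged within 5 kb, the KO events formed 5312 regions and the WT events 1284. Scaled to background reads, the KO share of events at least 2-fold apart was 73.0%, against 81.6% at the scale of the lists.

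H3K4me3 showed the opposite balance: 738 events were higher in KO and 5542 in WT, a KO share of 11.8% (10.97 to 12.6). The leading KO events clustered at few places. Between 22160317 and 22164092 on chromosome 16, 6 events together had 5887 reads in KO against 665 scaled reads in WT, a ratio of 8.85 (7.89 to 9.95), and the event at 22161065 within it reached 72.8 (32.6 to 195). Another group of 6 events lay at 95864061 to 95867849 on chromosome 11, with a ratio of 12.9 (10.7 to 15.8). On chromosome 6 the event at 49163888 had a ratio of 26.6 (16.8 to 45.3), and on chromosome 17 that at 49702602 had 30.5 (18.6 to 57.7). Further KO events were at 42127107 on chromosome 19 (6.93, 5.78 to 8.37), 110694040 on chromosome 13 (7.74, 6.12 to 9.90) and 119001182 on chromosome 2 (41.3, 22.1 to 102). The largest KO ratio, 115 at 22152389 on chromosome 16, rested on 1.3 scaled reads in WT, and its interval reached from 12.4 to 2780.

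Among events higher in WT, H3K4me3 at 59534389 on chromosome 19 had 2110 reads in WT and 146 scaled reads in KO, a ratio of 14.4 (12.8 to 16.3). At 63706559 on chromosome 4 the ratio was 181 (105 to 325), and at 63707191 beside it 67.1 (49.0 to 92.2). The event at 123641994 on chromosome 8 had a ratio of 41.2 (32.3 to 53.3), that at 43597691 on chromosome 18 had 120 (77.1 to 202), and that at 54290021 on chromosome 2 had 26.6 (21.8 to 32.9). At 149471006 on chromosome X, KO had 0 reads against 237 in WT, a ratio of 172 with KO set to the floor of 3 reads (lower limit of the interval 138). The longest WT region, 115889062 to 115901882 on chromosome 2, held 8 events with a ratio of 3.10 (2.96 to 3.26). At 52202223 to 52211001 on chromosome 6, 9 events gave a ratio of 2.91 (2.80 to 3.04). The median ratio was 4.10 in the KO list (2.85 and 6.97) and 3.01 in the WT list (2.55 and 4.16). WT events lay close together, so that 5542 events formed 2354 regions, and 738 KO events formed 618. The balance moved with the scale: in units of background reads, 738 KO and 1668 WT events were at least 2-fold apart, a KO share of 30.7%, against 719, 5182 and 12.2% at the scale of the lists. The median KO event was then 6.77-fold higher in KO, the median WT event 1.49-fold higher in WT, and 607 of the 5542 fell below 1.

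H3K36me3 had 1709 events higher in KO and 3341 higher in WT, a KO share of 33.8% (32.5 to 35.2). Merged within 5 kb they formed 989 and 1705 regions, and at a −log10 q of at least 5 there were 326 and 1308 events, a KO share of 19.95%. The longest KO region of this mark, 138088351 to 138131146 on chromosome 7, spanned 42796 bp with 28 events and a ratio of 4.05 (3.68 to 4.46). The region with the most leading KO events was 48782169 to 48795935 on chromosome 6, with 16 events and a ratio of 6.46 (5.81 to 7.19). Other long KO regions lay at 157951585 to 157970363 on chromosome 2 (4.07, 3.64 to 4.55) and 118032326 to 118046376 on chromosome 13 (4.46, 3.93 to 5.07). At 80300458 on chromosome 16, WT had 0 reads against 65 in KO, a ratio of 37.7 with WT set to the floor of 3 reads (lower limit 29.8). The KO event with the largest −log10 q, at 3026962 on chromosome 9, had 2317 reads in KO and 843 scaled reads in WT, far above the median of 40 in KO, and a ratio of 2.75 (2.57 to 2.94). The event beside it, at 3027593, also had many reads, 874 against 392, with a ratio of 2.23 (2.02 to 2.47). Whether reads map uniquely there was not examined.

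Among WT events of H3K36me3, those on chromosome 4 led: the event at 137302305 had a ratio of 23.7 (11.4 to 59.6), and the region at 137333868 to 137350869 held 14 events with a ratio of 13.3 (10.1 to 17.7). The event at 62983032 on chromosome 4 had a ratio of 22.6 (9.53 to 70.5), and that at 63867157 on chromosome 9 had 7.46 (4.82 to 12.4). A region at 83977078 to 83994553 on chromosome 6 had a ratio of 6.81 (5.22 to 8.97), and one of 19 events at 28356513 to 28373747 on chromosome 19 had 4.04 (3.65 to 4.49). At 34325768 on chromosome 19, KO had 0 reads against 140 in WT, a ratio of 27.5 with KO set to the floor of 3 reads (lower limit 22.1). The median ratio was 4.06 in the KO list (3.11 and 6.01) and 3.64 in the WT list (2.76 and 5.83). Events of this mark had few reads: at least 50 reads in the higher genotype were reached by 563 KO and 2688 WT events, which gave a KO share of 17.3%. KO reads had been multiplied by 1.70 to match WT, so this fixed minimum was stricter for KO. The 2 lists of this mark came from different programs, GPS for KO and GEM for WT, so this share also reflects any difference between the programs.

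The marks were then compared at the same places. Of the 738 H3K4me3 events higher in KO, 381 (51.6%, 48.0 to 55.3) had an H3K27ac event higher in KO within 1 kb, against a median of 5 and a maximum of 15 in 10000 random placements, and 0 had an H3K27ac event higher in WT. Of the 5542 H3K4me3 events higher in WT, 392 (7.07%, 6.41 to 7.78) had an H3K27ac event higher in WT within 1 kb, against a random median of 9, and 3 had one higher in KO. The shares of 51.6% and 7.07% do not compare how closely the marks go together in KO and WT. The H3K27ac lists held 8323 KO and 1765 WT events, and the H3K4me3 lists depend on the scale. Most H3K27ac events had no such neighbour. Beside an H3K4me3 event of the same direction lay 384 of 8323 KO events (4.61%) and 233 of 1765 WT events (13.2%). Beside H3K36me3 the shares were 0.853% and 2.15%. Counted from H3K27ac, 617 of 619 neighbour relations with H3K4me3 ran in the same direction, 99.7% (98.8 to 100.0). H3K27ac and H3K36me3 shared direction in 109 of 118 (92.4%, 86.0 to 96.5), and H3K4me3 and H3K36me3 in 252 of 255 (98.8%, 96.6 to 99.8). With directions shuffled within chromosomes, the highest of 1000 shuffles gave 67.7%, 83.1% and 92.9%.

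Within chains of events at most 10 kb apart, 63 regions had all 3 marks higher in KO and 60 had all 3 higher in WT, while 10 regions with 3 marks had both directions. Far more regions held 1 mark only, 4340 higher in KO and 3540 higher in WT. On chromosome 16, 22141272 to 22168785 was higher in KO with 8 H3K4me3, 4 H3K27ac and 6 H3K36me3 events, and its largest ratios were 115, 19.3 and 38.2. On chromosome 6, 49144759 to 49167522 reached 26.6 for H3K4me3, 22.6 for H3K27ac and 71.1 for H3K36me3. On chromosome 11, 95855474 to 95879346 reached 70.5, 13.9 and 13.8 for the same marks, and on chromosome 17, 49650758 to 49709898 reached 56.8, 14.7 and 40. The KO region with most events, 157935717 to 157994170 on chromosome 2, held 31, of which 20 were H3K36me3 events. Higher in WT, 43588657 to 43598344 on chromosome 18 had largest ratios of 215 for H3K4me3, 34.6 for H3K27ac and 29.4 for H3K36me3 among events with reads in both genotypes. An H3K36me3 event within it, at 43589221, had 81 reads in WT and 0 in KO (lower limit of the interval 12.6). The WT region with most events, 54272952 to 54330491 on chromosome 2, held 26, with ratios up to 26.6, 5.59 and 31.2. Others were 102750985 to 102769518 on chromosome 15 (57.1, 5.99 and 60.8), 63701485 to 63707719 on chromosome 4 (181, 4.98 and 28.5) and 59357141 to 59385278 on chromosome 6 (79.1, 14.0 and 23.4). Largest ratios often rest on few reads in the lower genotype, and those of shared regions leave out events with 0 reads there.

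**Figure D1:**
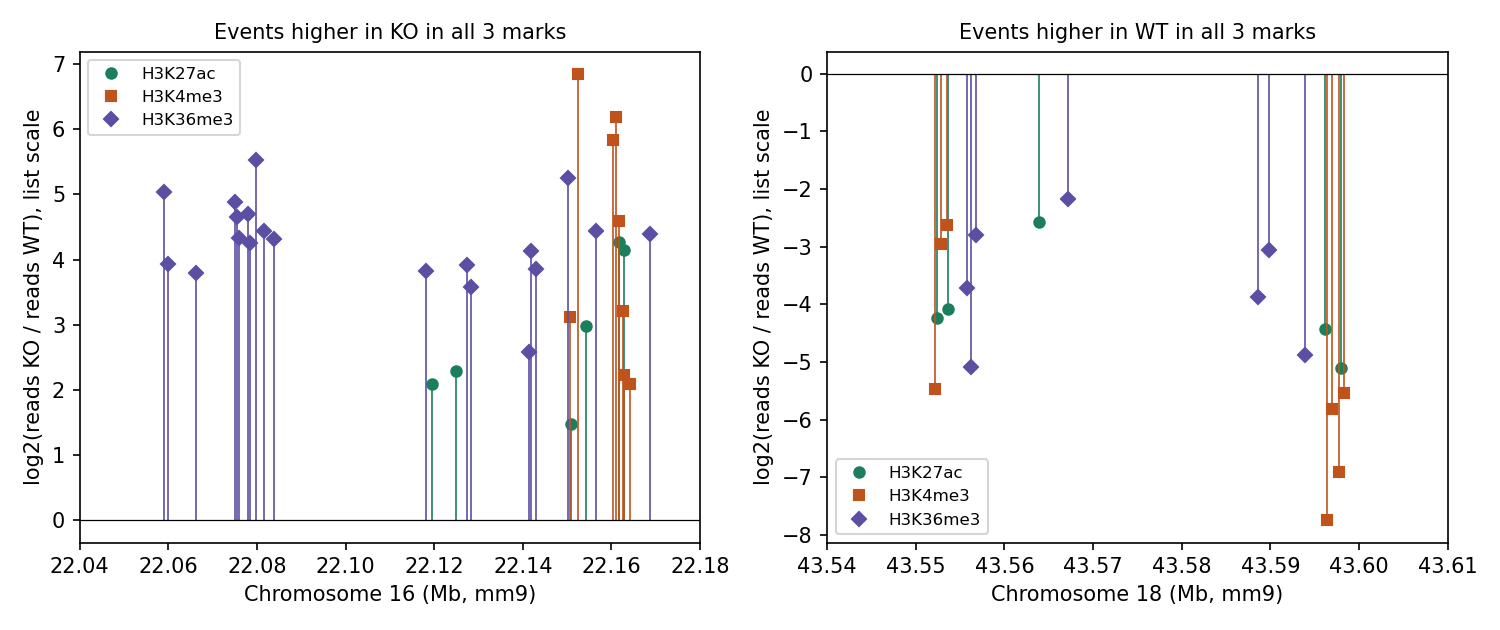
Events around 2 regions with all 3 marks higher in KO (left, chromosome 16) or in WT (right, chromosome 18), by position in Mb (mm9) and log2 ratio of KO to WT reads at the scale of each list. Each point is 1 event of the lists, coloured by mark, events with 0 reads in the other genotype are not drawn, and no event of the opposite direction falls in either panel.

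The direction of events differed between chromosomes. The KO shares of the 20 chromosomes correlated between marks, with Pearson's r of 0.722 for H3K27ac and H3K4me3, 0.797 for H3K27ac and H3K36me3, and 0.882 for H3K4me3 and H3K36me3 (0.674, 0.806 and 0.799 without chromosomes 9 and 12). Spearman's rho was 0.744, 0.770 and 0.877. At the scale of the lists, the KO share on chromosome 9 was the lowest of the 20 chromosomes in each mark: 44.4% for H3K27ac (118 of 266 events, 38.3 to 50.6), 0.775% for H3K4me3 (11 of 1420, 0.387 to 1.38) and 3.41% for H3K36me3 (22 of 646, 2.15 to 5.11). On chromosome 12 it was the highest: 95.7% (687 of 718, 93.9 to 97.0), 47.3% (62 of 131, 38.5 to 56.2) and 88.9% (192 of 216, 83.9 to 92.7). Low shares were also seen on chromosome X, with 61.0%, 3.18% and 4.41%, and on chromosome 19, with 74.0%, 1.81% and 10.3%. With events merged within 5 kb, the H3K4me3 shares were 2.01% on chromosome 9, 6.45% on X and 4.14% on 19, and the H3K36me3 share on X was 7.23%. The intervals treat clustered events as independent. All 13 bins of 10 Mb on chromosome 9 had more WT than KO events for H3K4me3 and for H3K36me3, while for H3K27ac 7 bins had more KO and 5 more WT events. These directions depend on the scale. In units of own background, the 1409 H3K4me3 events of WT on chromosome 9 had a median ratio of 1.14, against 2.94 at the scale of the lists. Their lower quartile was 0.982, so many of them were then higher in KO. On the other chromosomes except 12, WT events were the majority in 207 of 241 bins for H3K4me3, 141 of 238 for H3K36me3 and 26 of 240 for H3K27ac. On chromosome 12, events in the first 50 Mb were higher in KO in 37 of 45 for H3K4me3 (82.2%, 67.9 to 92.0) and 135 of 135 for H3K36me3, and from 50 Mb on in 25 of 86 (29.1%, 19.8 to 39.9) and 57 of 81 (70.4%, 59.2 to 80.0). For H3K27ac the shares of both parts were close, 97.3% (95.2 to 98.6) and 93.6% (90.3 to 96.0).

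**Figure D2:**
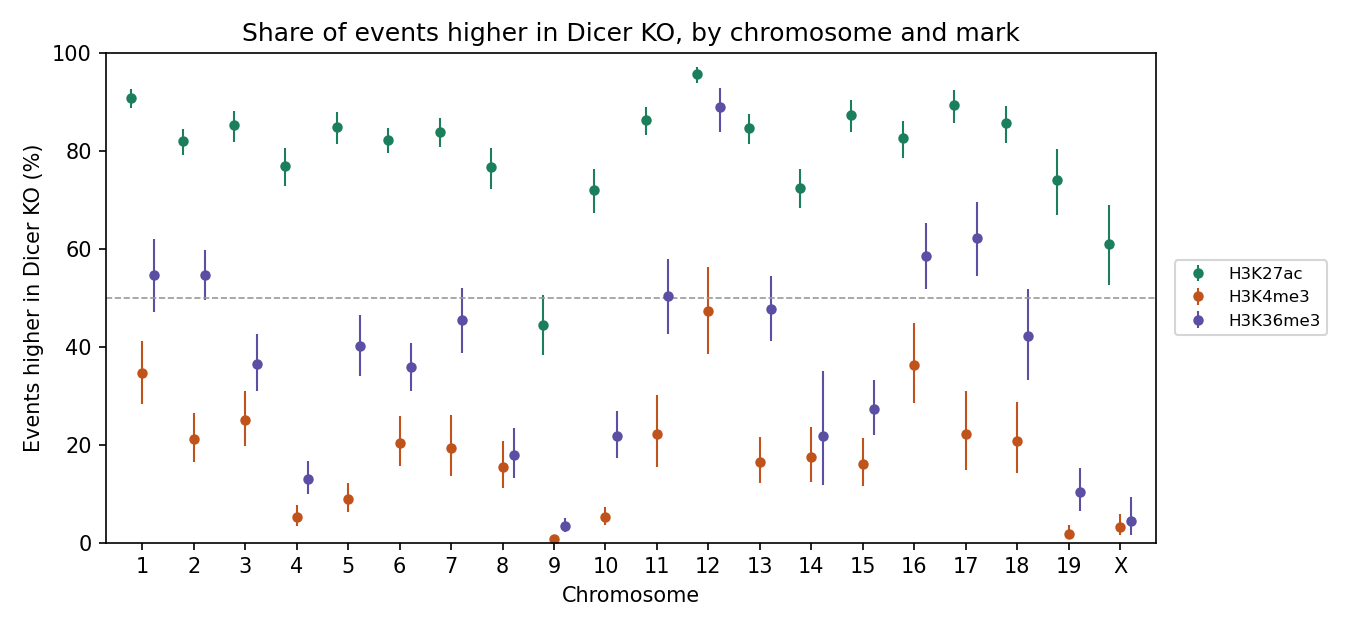
Percent of events higher in KO on each chromosome at the scale of the lists, for the 3 marks, with exact 95% binomial intervals (counting error only). The dashed line marks 50%, and chromosome 9 has the lowest and chromosome 12 the highest share in each mark.

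**Figure D3:**
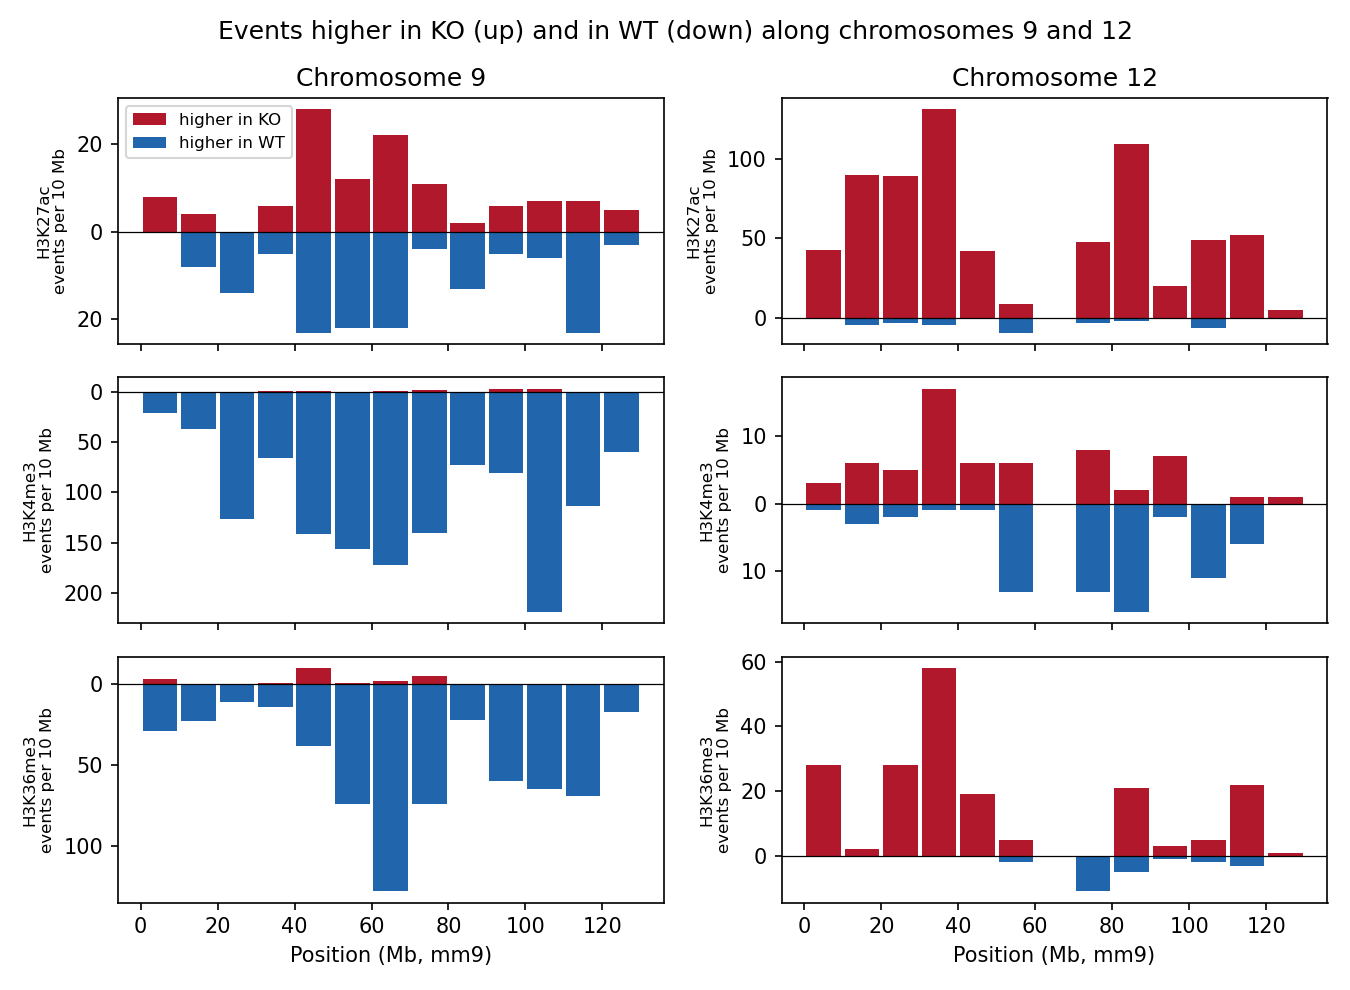
Number of events per 10 Mb along chromosomes 9 and 12 (mm9), with events higher in KO drawn upward and events higher in WT downward, 1 row per mark and a separate scale in each panel. At the scale of the lists, H3K4me3 and H3K36me3 events are mostly higher in WT along the whole of chromosome 9, and on chromosome 12 H3K36me3 events of the first 50 Mb are all higher in KO.

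Background reads also differed between chromosomes. Relative to the median chromosome, the KO to WT ratio of background reads on chromosome 9 was 0.632 in the H3K27ac lists and 0.654 in the H3K4me3 lists, and on chromosome 12 it was 1.27 and 1.20. Chromosome 10 had 0.820 and 0.834, chromosome 19 had 0.889 and 0.785, and chromosome X had 0.879 and 0.857. Across the 20 chromosomes, which are not independent samples, the ratios of the 2 marks correlated with Pearson's r of 0.922 and Spearman's rho of 0.811, and without chromosomes 9 and 12 with 0.823 and 0.740. The background ratio correlated with the KO share with r of 0.886 for H3K27ac and 0.894 for H3K4me3, and without chromosomes 9 and 12 with 0.758 and 0.886, where rho was 0.7503 and 0.862. The H3K27ac background ratio correlated with the KO share of H3K36me3 with r of 0.832 and rho of 0.780. These 7 relations across chromosomes are descriptions, given without p-values.

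**Figure D4:**
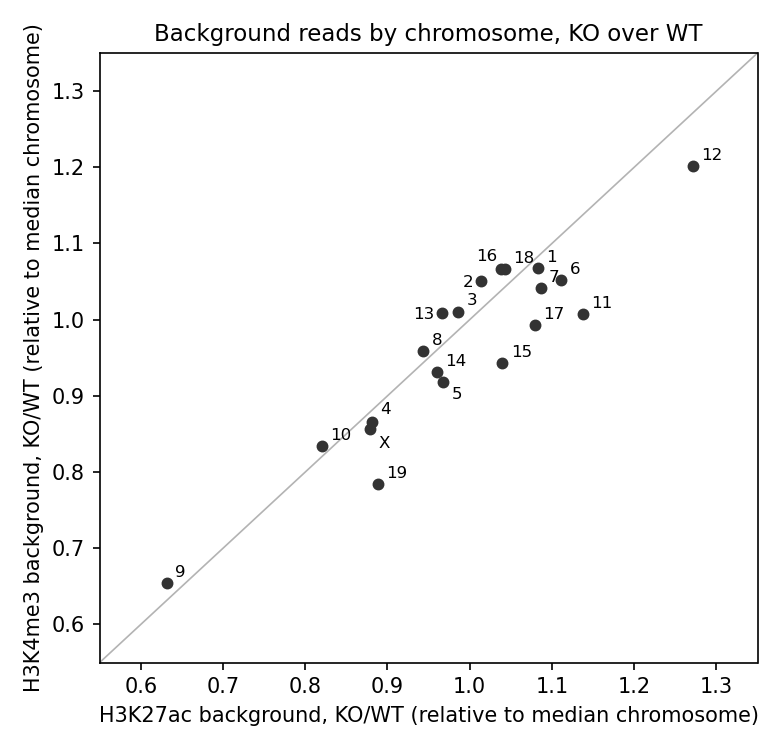
KO to WT ratio of background reads per chromosome, relative to the median chromosome, in the H3K27ac lists (horizontal) and the H3K4me3 lists (vertical). Each point is 1 chromosome, the line marks equal ratios, and chromosomes 9 and 12 lie at the low and the high end.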

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

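The filters, distances and merging below were chosen before the data were examined. Leaving out chromosomes 9 and 12, scaling to background reads, counting merged regions once in the shares of direction, and giving the KO share per mark under each filter were chosen after seeing the data. The KO share stayed above 50% for H3K27ac and below 50% for H3K4me3 and H3K36me3 under every alternative tried. Each alternative used only events that had passed at the authors' scale, so events that could reverse the balance may be missing. For H3K36me3 no background scale was tried. The median ratio per list stayed within its quartiles with 1 read added and at 50 reads or more. Scaled to own or median background, it fell outside them in 2 lists, to 2.10 and 2.15 for H3K27ac in KO and to 1.49 and 1.78 for H3K4me3 in WT. Of the 42 alternative counts of events per list, 33 stayed within 1.5 times the main count. Random placement and shuffling were done within chromosomes throughout. The placement takes no account of where marked chromatin lies, so it does not exclude a difference between whole chromosomes as a source of the overlaps. The shuffles keep the positions and bear only on the shares of direction. No paired analysis was possible because the lists give 1 value per genotype and mark, and no replicate could be left out for the same reason. Gene lists and location relative to genes were not run, for want of an annotation in mm9. Library depth is unknown, and reads per event were fewest for H3K36me3, with a median of 40 in KO.

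Counts fell by construction under stricter rules and merging. Merged within 5 kb, they were 5312 for H3K27ac in KO, 2354 for H3K4me3 in WT, and 989 in KO and 1705 in WT for H3K36me3. Merged within 1 kb, they were 2597 for H3K4me3 in WT and 2189 for H3K36me3 in WT. At a −log10 q of at least 5, H3K36me3 kept 326 KO and 1308 WT events, and at 50 reads or more 563 KO events, a minimum that is stricter for KO, whose reads were fewer. Counts of events at least 2-fold apart were compared between scales only. For H3K27ac in KO they were 7453 at the scale of the lists, 4637 with each chromosome's own background and 4925 with the median background. For H3K4me3 in WT they were 5182, 1668 and 2041.

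The KO share of H3K27ac was 81.6% at 2-fold or more and 73.0% with own background as well. That of H3K4me3 was 9.89% at a −log10 q of at least 5, 14.1% without chromosomes 9 and 12, and 30.7% at 2-fold with own background. That of H3K36me3 was 19.95% at a −log10 q of at least 5, 17.3% at 50 reads or more, and 35.7% without chromosomes 9 and 12. Shares of neighbours in the same direction were 98.8% for H3K27ac and H3K4me3 within 5 kb, 85.7% for H3K27ac and H3K36me3 at the stricter q, and 100% for H3K4me3 and H3K36me3 within 200 bp. The other 15 of 18 stayed within the main interval.

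Shares of events with a neighbour moved with the distance, as its construction implies. For H3K27ac beside H3K4me3 they were 2.25% within 200 bp and 6.68% within 5 kb in KO, and 9.12% and 16.4% in WT. For H3K27ac beside H3K36me3 they were 0.132% and 5.29% in KO, and 0.170% and 10.2% in WT. For H3K4me3 beside H3K36me3 they were 0.271% and 11.7% in KO, and 1.498% and 15.7% in WT. At the stricter q they were 3.81% for H3K27ac beside H3K4me3 in KO, 0.181% and 0.758% for H3K27ac beside H3K36me3 in KO and WT, and 0.522% and 3.02% for H3K4me3 beside H3K36me3. The stricter q also shortened the lists of possible neighbours, for H3K36me3 from 1709 to 326 events in KO and from 3341 to 1308 in WT. Fewer possible neighbours can by themselves lower these shares, and how far they did was not tested.

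Of 120 alternative KO shares of single chromosomes, 28 left the main interval, all on merging within 5 kb, which weighs dense clusters of events less. For H3K4me3 they rose to 42.8%, 29.0%, 39.4%, 11.2%, 16.4%, 31.5%, 28.3%, 26.4%, 2.01% and 11.2% on chromosomes 1 to 10, to 28.6%, 30.4%, 28.0%, 46.8%, 31.0%, 36% and 4.14% on chromosomes 13 to 19, and to 6.45% on X. For H3K27ac they were 88.5% on chromosome 1 and 78.4% on 6. For H3K36me3 they were 49.5% on chromosome 2, 45.8% on 3, 40.9% on 6, 23.4% on 8, 82.8% on 12, 34.1% on 15, 52.9% on 18 and 15.4% on 19. Merging took 4 shares across 50%, each with a main interval that included 50%: H3K4me3 on chromosome 12 (47.3% to 54.7%), and H3K36me3 on chromosomes 2 (from 54.7%), 13 (47.8% to 51.8%) and 18 (from 42.2%).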

Other observations

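Of 81 regions with both directions in chains of events at most 10 kb apart, 74 combined an H3K27ac event higher in KO with an H3K4me3 or H3K36me3 event higher in WT, 0 combined H3K27ac higher in WT with another mark higher in KO, and 7 held no H3K27ac event. At 86181982 to 86230962 on chromosome 12, 10 H3K27ac events were higher in KO beside 4 H3K4me3 events higher in WT, while 1 H3K4me3 event was higher in KO and H3K36me3 had 3 events in each direction. At 105931999 to 105939229 on chromosome 12, 2 H3K4me3 events were higher in WT, with a ratio of up to 170, and 1 H3K27ac event was higher in KO with a ratio of 2.29. Whether this region overlaps the Dicer gene, where KO may lack sequence, was not checked, so it cannot be read as a change of chromatin. At 100249907 to 100280478 on chromosome 11, 5 H3K27ac events were higher in KO beside 7 H3K4me3 and 4 H3K36me3 events higher in WT. These regions were chosen after their values were seen. The long lists of H3K27ac in KO and of H3K4me3 and H3K36me3 in WT favour this combination by number. Whether list lengths account for 74 against 0 was not tested.

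Sizes of change went together in part. For 233 H3K27ac events higher in WT with an H3K4me3 event higher in WT within 1 kb, the log ratios correlated with r of 0.599 and rho of 0.614, across events that are not independent. For the 384 such events higher in KO, r was 0.328 and rho 0.272. The median H3K4me3 ratio beside H3K27ac was 7.83 in WT and 4.17 in KO, where the median H3K27ac ratio of the same pairs was 3.61 and 3.25, each at the scale of its list. Chromosome X gave 4 of the 5 largest H3K4me3 ratios in WT, and held 304 WT and 10 KO events of that mark.

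Of the tests below, that of neighbouring marks was set before its result was seen, and those of chromosome 9, of the scale and of chromosome 12 were chosen after. The low KO share on chromosome 9 in all 3 marks could come from a difference between the clones in copies, or read yield, of whole chromosomes. The KO to WT ratio of background reads on chromosome 9 was 0.632 relative to the median chromosome for H3K27ac and 0.654 for H3K4me3, the lowest of 20 in both, as that explanation needs. Changes at single sites stay open beside it. In units of own background, 7.38% (6.07 to 8.87) of the 1409 WT events of H3K4me3 on chromosome 9 stayed at least 2-fold apart, against 37.8% (36.4 to 39.3) of the 4133 elsewhere. The median ratio of these chromosome 9 events was 1.14 in those units (quartiles 0.982 and 1.31), against 2.94 at the scale of the lists. Elsewhere the median was 1.67 in those units. The typical listed event of chromosome 9 was thus near even once its background was used. Share and median both fall with every weak event that enters the list, so they do not decide about the stronger sites. In number, the 104 events of chromosome 9 at least 2-fold apart in those units lay within the range of the other chromosomes, 34 to 135. The background values come from the same libraries, no genomic input was analysed here, and a genotype effect on a whole chromosome stays open, untested.

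Neighbouring events of different marks were higher in the same genotype, 99.7% of them for H3K27ac and H3K4me3. Chromosome-wide differences alone are argued against, since the highest of 1000 shuffles within chromosomes gave 67.7%. Copy differences of short segments, which would move all marks alike, were not tested and stay open beside an effect of the genotype or of the clone.

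The balance of events was opposite in H3K27ac and H3K4me3. The factor used in each list is a candidate explanation. In the H3K4me3 list of KO the wild type was multiplied by 2.15, while the background reads of KO were only 1.28 times those of WT on the median chromosome. In the H3K27ac list of KO the wild type was multiplied by 0.85, while the background reads of KO were 1.13 times those of WT. The list factors thus tilt the 2 marks in opposite directions, as the balance does. In units of own background the KO share of H3K4me3 events at least 2-fold apart was 30.7%, closer to even but still below 50%, and that of H3K27ac was 73.0%. This does not settle it, since the lists hold only events that passed at the authors' scale. H3K4me3 events of KO and H3K27ac events of WT that would pass at the background scale are not part of them. Both lists of each of these 2 marks came from 1 program, so a difference between programs does not by itself favour 1 genotype. Differences in enrichment between libraries stay open too.

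A further hypothesis was that proximal chromosome 12 differs from the rest of that chromosome. H3K4me3 directions were shuffled 10000 times among its regions, events merged within 5 kb (42 regions in the first 50 Mb and 53 beyond), and the largest gap in KO share over 9 boundaries had a one-sided permutation p of 0.0011. The chromosome and the mark had also been picked from the data, and multiplied by the 60 combinations of chromosome and mark the p was 0.066. Chance placement was therefore not excluded by this test of H3K4me3. The split was also present in H3K36me3, with 135 of 135 events higher in KO in the first 50 Mb and 57 of 81 beyond, which was not tested, and was small in H3K27ac, with 97.3% and 93.6%.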
